A study of Mus musculus with 2 samples.

How the data were processed

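The accessible DNA of mouse cerebellum was measured by DNase-seq, in which nuclei are treated with the nuclease DNase I and the cut ends are sequenced, so that positions cut often are those where DNA is exposed. The 2 samples were cerebellar tissue of male B6CASTF1/J mice aged 14 days. This strain is the first-generation cross of the laboratory strain B6 with the wild-derived strain CAST. Per the labels, they are biological replicates 1 and 2 of a single tissue. Both name the same donor record, and their descriptions read as different collections of males, so the spread between them is taken as that between 2 tissue preparations, with the number of animals in each not settled.

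Per the labels, the authors used the mm10 assembly. Per the file headers and descriptions deposited with each sample, the peaks, footprints and false discovery rates were all made from the alignments of that sample alone, so the replicates can be compared as separate calls. The aligner, the peak caller and their versions are not given in the sources used here. The authors deposited 2 peak lists per sample. In the shorter one every peak held a position with a false discovery rate of at most 0.001, and in the longer one of at most 0.05, when each peak was checked against the rates of its own sample. The deposited peak value is a signal on a linear scale, and its normalization is not given in the sources used here. Below 200 steps, 100% of the signal values of each sample were whole multiples, within 0.02 of a step, of a single step of 0.003683 in replicate 1 and 0.004542 in replicate 2. A signal of 1 thus corresponds to 271.5 steps in replicate 1 and 220.2 in replicate 2. If each step is a single read, this is proportional to the depth. The number of reads is not given in the sources used here, and the ratio of these values, 1.23, is used only as a relative depth. The deposited false discovery rates, read here as p-value or q-value type quantities, list only positions under 0.05. Footprints, short stretches protected from cutting inside accessible DNA, were deposited as positions with the constant 0.01 in place of a value.

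Everything that follows was computed from those files with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The shorter peak list of each sample was the main list. Genes came from the GENCODE M21 annotation and sequence from the GRCm38.p6 assembly, which has the coordinates of mm10. All peaks lay inside the 21 chromosomes of that sequence. A peak or footprint counted as found in both replicates when it overlapped one of the other replicate by at least 1 bp. Agreement was set against 20 random placements of the peaks on their own chromosomes, and against 20 random placements of each footprint inside its own peak. Overlapping peaks of both replicates were merged, and merged stretches with a peak of each replicate are called shared regions. A shared region took the highest peak signal of each replicate.

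A gene was called open at its promoter when a peak overlapped the window of 1 kb on either side of a transcription start of one of its protein-coding transcripts. There were 21851 protein-coding genes with 41438 such starts. Distal regions were shared regions more than 1 kb from any of 77161 annotated starts of any gene type. Distal peaks of a gene were counted over its annotated body extended by 10 kb on both sides. Peak and footprint positions were classed by their midpoints, in the order promoter, exon, intron and intergenic.

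The design holds a single group, so no groups of samples were compared and no test used the replicates as its units. Before the data were examined, 21 gene lists and 22 sequence motifs were fixed, together with each test and its alternatives. The lists were markers of granule neurons, granule progenitors with the response to Sonic hedgehog (SHH), Purkinje cells, GABAergic interneurons, unipolar brush cells with cerebellar nuclei, astrocytes with Bergmann glia, the oligodendrocyte lineage, microglia, vascular cells, and choroid plexus with ependyma and meninges, then general neuronal, immediate early, isthmic and hindbrain patterning, forebrain patterning, Hox cluster, housekeeping, liver, striated muscle, germ cell, lymphocyte and olfactory receptor genes. All 1401 listed symbols were found in the annotation. The share of a list open in both replicates was set against all other protein-coding genes with a two-sided Fisher's exact test. The mean of log2(distal peaks + 1) of a list was set against 10000 random lists of the same size, matched on the decile of gene length, with a two-sided permutation p. The smallest such p is 0.0002. Motifs, written as consensus sequences with degenerate bases, were searched on both strands in windows of 30 bp around the midpoints of footprints of replicate 1 found in both replicates. The control windows lay 100 bp to either side and touched no footprint of either replicate. Matches under a footprint were thus kept out of the controls, which did not have to lie in peaks. Part of the size of a ratio can come from this choice, and how much was not measured. The shares were compared by two-sided Fisher's exact tests. Each family of tests was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Genes and footprints are the units of these tests, neighbouring ones are not independent, and the p-values describe these libraries only. Intervals on motif shares are 95% Wilson intervals, and they cover counting error only.

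The genes named were set before the data were examined. They are the 2 members of each list with the most shared distal peaks and the 2 with the fewest, the 5 genes with the most, and the 10 promoter and 10 distal regions with the best worse rank of signal in the replicates. Some genes that this rule selects are not reported here. Any other gene is named as an example chosen after its values were seen. The 2 tests of gene lists were tested on simulated data with the real genes, and the motif test on random sequence. With 5 of 20 lists made open in 99% of their members, the promoter test over 21851 genes recovered 64.0% of the changed lists and called 2.33% of the unchanged ones. With 1 added to the distal peaks of each gene of 5 lists and the sum tripled, the test over the same genes recovered 100% of the changed lists and called 2.33% of the others. This planted change is larger than tripling, so the recovery does not describe the power for smaller differences. With 5 motifs planted in 1% of 50000 random windows each, the motif test recovered 100% of them and called 1.47% of the others. Footprint and control windows of this simulation had the same uniform base composition, so the effect of a difference in GC content was not tested by it. Most motifs stood in less than 1% of the real footprint windows. The alternatives were other promoter windows, flanks, overlaps, motif windows and control shifts, the longer peak list, the peaks at or above the median signal of each list, equal numbers of top-ranked peaks, other matching of random lists, control windows matched on GC content, and each replicate on its own. An alternative without olfactory receptors and one without genes annotated over more than 2 Mb were added after the data had been seen. Allele-specific accessibility was not analysed here. Reads of CAST alleles that differ from the reference can be lost in alignment, and how the authors treated them is not given in the sources used here.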

Results

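Accessible DNA of the cerebellum was mapped in 2 biological replicates of tissue from male mice at 14 days of age, when granule neurons are still being born and are maturing. The files listed 155183 peaks in replicate 1 and 143390 in replicate 2, with median widths of 200 and 180 bp. The peaks covered 33.4 Mb and 25.9 Mb. They listed 709533 footprints in replicate 1 and 573782 in replicate 2, with median widths of 10 and 12 bp. The relative depth read from the steps of the signal was 1.23 times higher in replicate 1. The median peak signal was 0.696 in replicate 1 and 1.04 in replicate 2. The labels name 1 group, so the comparisons were between the replicates, between classes of sequence and between groups of genes. Coordinates are those of mm10.

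The strongest accessible regions were found in both replicates, and the weak ones often in 1 only. Of the peaks of replicate 1, 118368 (76.3%) overlapped a peak of replicate 2, and 119659 (83.5%) of the peaks of replicate 2 overlapped one of replicate 1. Random placement gave 2.26% and 2.41%. Above the 75th percentile of signal the shares were 99.6% and 98.4%, and up to the 25th percentile they were 39.999% and 61.0%. Peaks without a partner had a median signal of 0.317 in replicate 1, against 0.969 for those with one, and the medians in replicate 2 were 0.491 and 1.28. Of those without a partner, 47.5% in replicate 1 and 54.9% in replicate 2 overlapped the longer list of the other replicate. The peaks merged into 115661 shared regions, and across these regions, which are not independent, Spearman's rho of the signals was 0.941. The signal was higher in replicate 2 in 82.5% of the shared regions, with a median log2 difference of 0.51 as deposited (SD 0.51 across regions) and 0.21 with each signal counted in steps of its own replicate.

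**Figure D1:**
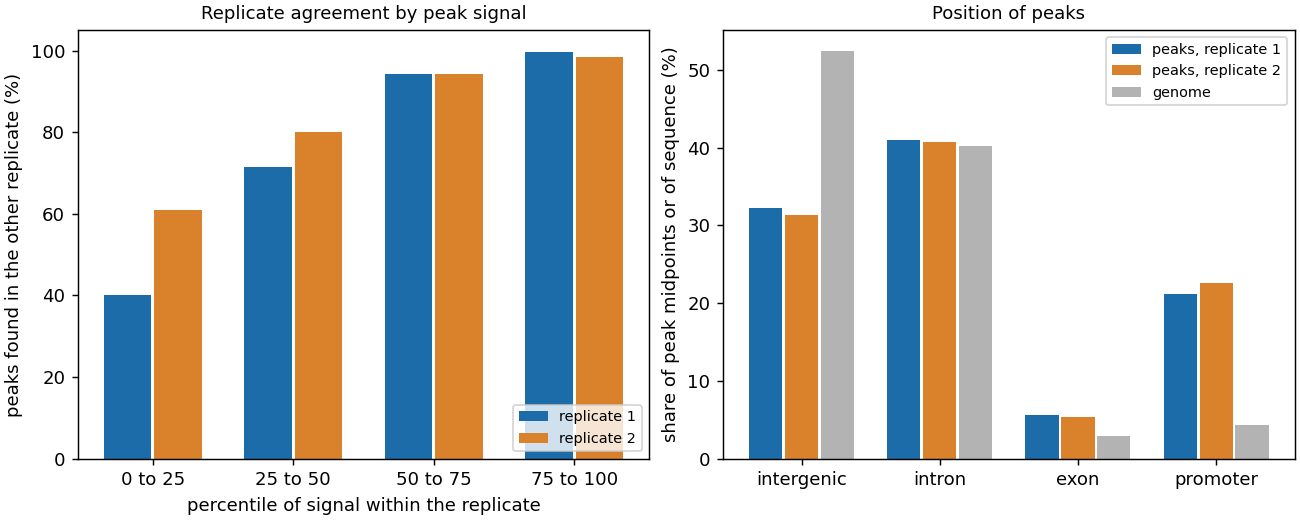
The left panel plots the percentage of peaks of each replicate that overlap a peak of the other, by percentile of signal within the replicate, and the right panel plots the percentage of peak midpoints in each class of sequence beside the percentage of the genome in that class. Sharing goes from 39.999% to 99.6% in replicate 1 and from 61.0% to 98.4% in replicate 2, and promoters hold 21.1% and 22.5% of the peaks on 4.37% of the genome.

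Peaks were concentrated at promoters, although most regions were distal. Promoters held 21.8% ± 0.99 (SD, n = 2) of the peaks and 4.37% of the genome. Introns held 40.8% ± 0.14 of the peaks, exons 5.51% ± 0.17 and intergenic sequence 31.8% ± 0.68 (SD, n = 2), and these classes made up 40.3%, 2.91% and 52.5% of the genome. Of the shared regions, 88748 (76.7%) lay more than 1 kb from any transcription start. Distal regions were weaker, with a median signal of 0.843 in replicate 1 and 1.13 in replicate 2, against 1.87 and 2.75 at promoters. Chromosome 11 was the most densely occupied, with 67.4 shared regions per Mb, and chromosome X had 17.9 per Mb. In these male animals, which carry a single X, the median signal on the X was 0.557 of the autosomal median at promoters and 0.584 at distal regions in replicate 1, and 0.611 and 0.540 in replicate 2. Chromosome Y held 23 shared regions.

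Ordered by the worse of its 2 ranks of signal, the first promoter region, with rank 3 in replicate 1 and rank 1 in replicate 2, lay at chromosome 17, 6430021 to 6430180, at a start of Dynlt1b, which encodes a dynein light chain, with signals of 31.7 in replicate 1 and 77.1 in replicate 2. It was followed by regions at Hjurp (28.3 and 59.7), a chaperone of the centromeric histone, at Bahcc1 (24.7 and 60.4) and at Fzr1 (19.2 and 44.2), an activator of the anaphase-promoting complex. The others of the first 10 lay at Gys1, Amd1, Nup107, Eif5a and Rragc and at the noncoding RNA gene 1700096K18Rik. The first distal region lay at chromosome 17, 27240641 to 27240860, in an intron of the annotated transcript AC141882.2, with signals of 23.9 and 55.5. The next were in introns of Mid1 on the X, at 169998241 to 169998420 (22.2 and 47.2), and of Vps37c on chromosome 19, at 10709501 to 10709660 (22.2 and 38.2). Another of the 10 lay 1206 bp from the nearest start, that of Ptma. Dynlt1b belongs to a family of near-identical copies and Mid1 spans the boundary of the pseudoautosomal region, so reads at both can be shared between copies.

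Promoters of granule neuron, granule progenitor and general neuronal genes were open without exception, while those of microglia, Hox clusters and other organs mostly had no peak. The samples were tissue of mixed cell types, so a promoter without a peak can still be accessible in a rare cell type. In both replicates 14091 of 21851 protein-coding genes (64.5%) had a promoter peak. Replicate 1 had 14470 and replicate 2 had 14311, and 599 genes were open in 1 replicate only. All 15 granule neuron genes were open (adjusted p = 0.0037, Fisher's exact test), as were all 14 granule progenitor and SHH response genes (adjusted p = 0.0060). The 16 general neuronal, 16 immediate early and 16 housekeeping genes were open too (adjusted p = 0.0024 for each list, Fisher's exact test). Among granule neuron genes, the promoter of Cbln3, which encodes a synaptic organiser of the cerebellin family, had signals of 9.07 in replicate 1 and 24.4 in replicate 2. Gabra6, the alpha6 subunit of the GABA-A receptor of granule neurons, had 2.77 and 3.60. The promoter of Pax6, a transcription factor of the granule lineage, had 6.25 and 11.5. Among the progenitor genes, the Hedgehog coreceptor gene Boc had 2.98 and 7.56 and the Hedgehog-binding gene Hhip had 0.899 and 1.48. Top2a, a topoisomerase of dividing cells, went the other way from most regions, with 8.96 in replicate 1 and 3.61 in replicate 2. The early response gene Egr1 had 12.4 and 19.9.

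For the Purkinje, interneuron, unipolar brush cell, astrocyte, oligodendrocyte, vascular, choroid plexus and isthmic lists the promoter shares did not pass the test in both replicates. Of the Purkinje cell genes 12 of 16 were open (adjusted p = 0.47, Fisher's exact test), among them Rora, a nuclear receptor required for these cells (3.33 and 6.92). Pcp2 and Ppp1r17, examples chosen after their values were seen, had no promoter peak in either replicate. Of the GABAergic interneuron genes 12 of 13 were open (adjusted p = 0.062), of the unipolar brush cell and cerebellar nuclei genes 8 of 8 (adjusted p = 0.080), and of the astrocyte and Bergmann glia genes 12 of 15 (adjusted p = 0.31), all by Fisher's exact test. With all 8 of its genes open, the unipolar brush cell list had an unadjusted p of 0.057 (Fisher's exact test). A list of this size could thus not pass as higher in the main test. Some of these calls changed under an alternative: interneuron genes passed in replicate 1 alone (13 of 13, adjusted p = 0.011), unipolar brush cell genes with a window of 500 bp (adjusted p = 0.047) and astrocyte genes in the longer list (15 of 15, adjusted p = 0.0082, Fisher's exact test for each), with ranges over the alternatives of 0.011 to 0.46, 0.047 to 1 and 0.0082 to 0.46. With peaks above the median signal the interneuron and astrocyte shares turned to lower than other genes (6 of 13 and 6 of 15, 46.2% and 40% against 57.5%) and did not pass (adjusted p = 0.46 and 0.24, Fisher's exact test). Signals at several of them were low, as at Slc32a1, the vesicular GABA transporter (0.512 and 0.868), and Lmx1a, a transcription factor of the rhombic lip (0.519 and 0.450). Oligodendrocyte genes were open in 6 of 14 cases (adjusted p = 0.13, Fisher's exact test), with a peak at the myelin gene Mbp (1.26 and 2.59) and none at Cspg4. Vascular genes were open in 7 of 14 cases (adjusted p = 0.31, and 3 of 14 with peaks above the median signal, where the lower share passed, adjusted p = 0.018, within 0.018 to 1), choroid plexus, ependyma and meninges genes in 7 of 12 (adjusted p = 0.76), and isthmic and hindbrain patterning genes in 5 of 12 (adjusted p = 0.16, Fisher's exact test for each).

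Microglia, Hox cluster, liver, striated muscle, germ cell, lymphocyte and olfactory receptor lists had fewer open promoters than other genes. Microglia genes were open in 2 of 13 cases (adjusted p = 0.0012, Fisher's exact test), with a peak at Tmem119 (0.523 and 0.790) and none at Cx3cr1, the fractalkine receptor gene, Spi1 or C1qa. Hox genes were open in 4 of 39 cases (adjusted p = 2.8e-11, 7 of 39 in each replicate alone, and 0 with peaks above the median signal to 8 in the longer list), liver genes in 0 of 16 (adjusted p = 4.4e-07), striated muscle genes in 3 of 16 (adjusted p = 0.00084), germ cell genes in 2 of 15 (adjusted p = 0.00028) and lymphocyte genes in 0 of 14 (adjusted p = 2.6e-06, Fisher's exact test for each). Olfactory receptor genes were open in 34 of 1091 cases (3.12%, adjusted p computed as 0). Forebrain patterning genes were open in 6 of 16 cases (adjusted p = 0.055, Fisher's exact test), with Bcl11b at 1.41 and 2.03. This list depended on the library, because 14 of its 16 promoters were open in replicate 1 and 6 in replicate 2. Replicate 1 alone gave it a higher share than other genes by 21.3 percentage points (adjusted p = 0.13), and without olfactory receptors in the background its lower share passed the test (adjusted p = 0.024, Fisher's exact test for both, and 0.017 to 0.79 over the alternatives).

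**Figure D2:**
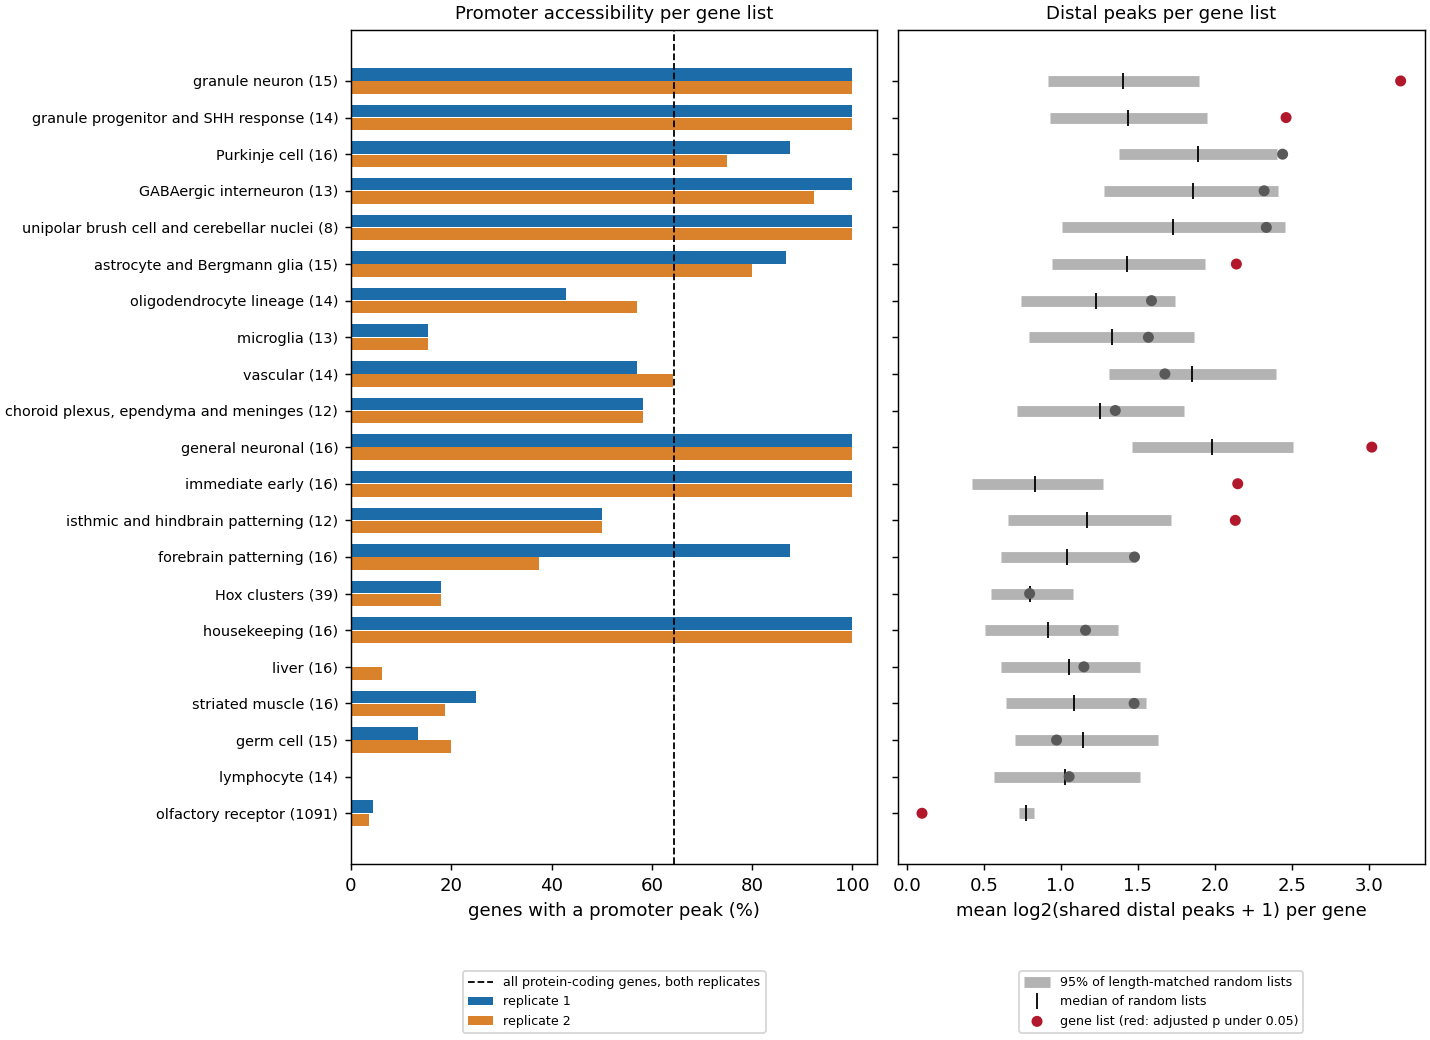
The left panel plots, for each gene list with its number of genes in brackets, the percentage of genes with a promoter peak in each replicate, with a dashed line at 64.5% for all protein-coding genes in both replicates. The right panel plots the mean log2(shared distal peaks + 1) per gene, with grey bars for 95% of random lists matched on gene length, and red points mark the 7 lists with an adjusted p under 0.05.

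Distal accessible regions were most enriched around granule neuron genes. Their count of shared distal peaks plus 1 was 3.49 times that of random lists of the same gene lengths, as a ratio of geometric means, and all 15 genes had at least 1 (adjusted p = 0.00084, permutation test, from the smallest p that the permutations can give). The ratios to random lists given below are of this same measure, so they are not ratios of the counts themselves. Pax6, at chromosome 2, 105668900 to 105697364, had 22 distal peaks, against a median of 2 for genes of its length, and Chn2, which encodes a chimaerin, had 24 against 10. Cbln3 and Gabra6 had 3 each, against 0 and 1. Immediate early genes followed with 2.49 times the random lists, general neuronal genes with 2.05 and granule progenitor genes with 2.03 (adjusted p = 0.00084 for each, permutation test). Examples were Egr1 with 7 against a median of 0, the neuronal splicing factor gene Rbfox3 with 72 and the synaptotagmin gene Syt1 with 29 against 10. These medians are those of the decile of gene length. The highest decile, with a median of 10, holds genes as unlike in length as Mbp and Gm20388, which is annotated over several Mb. So 10 is not the median of genes as long as Rbfox3 or Syt1, and matching on the decile left such differences in length in place. Gli2, a transcription factor of Hedgehog signalling, had 22 against 10 and Boc had 17 against 4, while Top2a had 0 against 2. With the median count the progenitor list did not pass (adjusted p = 0.064, permutation test).

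Isthmic and hindbrain patterning genes had 1.95 times the random lists in distal peaks plus 1 (adjusted p = 0.0028, permutation test), although 5 of their 12 promoters were open. En1, a homeobox gene of the midbrain and hindbrain boundary, had 9 against a median of 0 for its length. Pax5 had 18 against 10 with no promoter peak in either replicate. Astrocyte and Bergmann glia genes had 1.64 times the random lists (adjusted p = 0.020, permutation test), with 13 at the glutamate transporter gene Slc1a2 and 15 at Aldh1l1, whose promoter had no peak. The astrocyte call was lost with a flank of 50 kb (adjusted p = 0.13, permutation test), with the median count (0.42), with random lists not matched on length (0.061) and with peaks above the median signal (0.23), and over its alternatives it ran from 0.017 to 0.42. The isthmic call was lost without matching on length (adjusted p = 0.085, permutation test) and with peaks above the median signal (0.056), within a range of 0.00084 to 0.085. Olfactory receptor genes had 0.625 times the random lists in distal peaks plus 1 (adjusted p = 0.00084, permutation test, and 1 with the median count). As 999 of 1091 had no distal peak, this ratio understates the difference in the counts themselves.

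The other lists did not pass the test for distal peaks. Purkinje cell genes had 1.47 times the random lists (adjusted p = 0.099, permutation test), with 64 at Rora and 0 at Aldoc and Homer3. GABAergic interneuron genes had 1.38 times (adjusted p = 0.18, permutation test), with 31 at Sorcs3 and 24 at Nxph1, and unipolar brush cell and cerebellar nuclei genes had 1.52 times (adjusted p = 0.18), with 12 at Lmx1a and 9 at Calb2. In replicate 1 alone these 3 lists passed, with adjusted p of 0.023, 0.0033 and 0.0033 in the permutation test, and forebrain patterning genes passed too (0.00084, against 0.13 in both replicates). The ratios in replicate 1 alone were 1.66, 2.00, 2.53 and 3.66 for these 4 lists, and in replicate 2 alone 1.42, 1.30, 1.57 and 1.36, where none of the 4 passed; in both replicates the forebrain ratio was 1.36. Some of these lists also passed with both replicates under other settings. Purkinje genes did with the gene body alone (adjusted p = 0.017) and without matching on length (0.0070, permutation test for both). Interneuron genes did without matching on length (0.035), and forebrain genes with matching on promoter accessibility (ratio 1.45, adjusted p = 0.035, permutation test for both). Over their alternatives the adjusted p of the Purkinje, interneuron, unipolar brush cell and forebrain lists ran from 0.0070 to 1, 0.0033 to 0.81, 0.0033 to 0.74 and 0.00084 to 1 in the permutation test. The ratios were 1.29 for the oligodendrocyte lineage, 1.18 for microglia, 0.884 for vascular cells, 1.07 for choroid plexus, ependyma and meninges, 0.997 for Hox clusters, 1.18 for housekeeping, 1.07 for liver, 1.31 for striated muscle, 0.888 for germ cells and 1.02 for lymphocytes, with adjusted p from 0.18 to 0.97. Striated muscle genes passed as higher with a flank of 50 kb (ratio 1.88, adjusted p = 0.0056) and with matching on promoter accessibility (1.498, adjusted p = 0.035), and Hox genes as lower without matching on length (0.676, adjusted p = 0.0070, permutation test for each), within ranges of 0.0056 to 0.75 and 0.0070 to 1. Cx3cr1 had 15, over an annotated body that runs from 119901616 to 120069879 on chromosome 9. Over all genes, the highest counts were 357 at Gm20388 and 183 at Fgfr2, both annotated over several Mb, then 94 at Rbfox1, 92 at Ntm and 91 at Nav2. The first 2 reach across other genes, at 119910841 to 124345722 on chromosome 8 and 130162451 to 133123350 on chromosome 7.

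Footprints agreed between replicates more often than their peaks alone would give. Of the footprints of replicate 1, 365849 (51.6%) overlapped one of replicate 2, and 356227 (62.1%) of those of replicate 2 overlapped one of replicate 1. Inside peaks the shares were 62.4% and 69.7%, against 43.8% and 49.99% when each footprint was moved at random inside its own peak. With a reciprocal overlap of 50%, 269970 footprints of replicate 1 were shared.

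Of the 22 motifs, 13 were more frequent in shared footprints than in windows 100 bp away and 7 less frequent. The motif of CTCF, the protein of insulators and chromatin loops, stood in 6177 of 365845 footprint windows (1.69%, 95% interval 1.65 to 1.73) and in 20 of 394238 control windows, a ratio of 333 (interval 215 to 516, adjusted p computed as 0, Fisher's exact test), and footprints of replicate 1 alone gave 173 and those of replicate 2 alone 253. The motif of nuclear factor I (NFI), a family active in maturing granule neurons, stood in 262 footprint windows and 1 control window, a ratio of 282 with a counting interval of 39.6 to 2012 (adjusted p = 1.8e-81, Fisher's exact test), 116 and 171 with each replicate alone, and 80.2 with controls 200 bp away, of which 5 held the motif. Motifs of ZIC, zinc finger proteins of the granule lineage, stood in 1.17% of footprint windows and 0.207% of control windows (ratio 5.65, adjusted p computed as 0). The E-box of ATOH and NEUROD proteins stood in 0.847% and 0.295% (ratio 2.87, adjusted p = 4.4e-233, Fisher's exact test). Motifs of promoter factors were enriched as well, with ratios of 121.5 for NRF1, 21.3 for CREB, 15.5 for SP and KLF proteins, 8.72 for YY1, 7.11 for ETS proteins and 2.16 for NFY. The sizes depended on the choices: in replicate 1 alone the ratio was 56.1 for NRF1, 11.04 for CREB and 8.92 for SP and KLF, in replicate 2 alone 78.4 for NRF1, with controls matched on GC content 55.8 for NRF1, 4.69 for SP and KLF and 3.95 for YY1, and in distal footprints 36.9 for NRF1, 9.12 for CREB and 6.27 for SP and KLF. Over all alternatives that gave a ratio, the ratios ran from 173 to 435 for CTCF, 80.2 to 292 for NFI, 36.9 to 115 for NRF1, 9.12 to 23.4 for CREB, 4.69 to 14.3 for SP and KLF, 2.15 to 13.6 for YY1, 1.72 to 5.90 for ETS, 5.59 to 12.9 for RFX and 2.00 to 7.80 for REST, and ETS had 3.26 with controls 50 bp away. With controls matched on GC content NFI had no ratio, as its motif stood in 221 footprint windows and 0 control windows. RFX had a ratio of 10.1 (6.45 in replicate 1 alone), REST 5.03 (2.86 in replicate 2 alone) and GLI, the effector of Hedgehog signalling, 1.46 (adjusted p = 0.016, Fisher's exact test).

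The 7 motifs that were less frequent in footprints than beside them had ratios below 1. The ratio was 0.318 for GATA, 0.385 for TCF and LEF, 0.523 for SOX, 0.582 for POU, 0.733 for ROR, 0.754 for AP-1 and 0.830 for SRF (adjusted p from 7.9e-91 to 0.020, Fisher's exact test). In replicate 1 alone TCF and LEF had 0.582 and SRF did not pass (adjusted p = 0.051), in replicate 2 alone ROR did not (adjusted p = 0.31), and MEF2 passed in replicate 1 alone (ratio 1.18, adjusted p = 0.021, Fisher's exact test for each). With controls 50 bp away SRF did not pass (adjusted p = 0.12), with controls 200 bp away ROR did not (0.14) and MEF2 did (1.24, adjusted p = 0.038), and with windows of 50 bp AP-1 did not (0.970, adjusted p = 0.33) and ROR turned to 1.08 (adjusted p = 0.45, Fisher's exact test for each). MEF2 had a ratio of 1.00 (adjusted p = 1, Fisher's exact test), and the motif of HNF1, a factor of liver and kidney, was found in 0 footprint and 0 control windows. Footprint windows held 58.9% GC and control windows 48.7%, and matching on GC content changed several of these results. In matched windows POU and SRF were more frequent in footprints (ratios 1.40 and 1.41, adjusted p = 0.00066 and 0.00017), MEF2 was too (2.77, adjusted p = 1.2e-13), and ROR, AP-1, GLI and REST did not pass (adjusted p = 0.058, 0.085, 0.71 and 0.26, Fisher's exact test). GATA, TCF and LEF, and SOX stayed lower (ratios 0.589, 0.661 and 0.810). In footprints more than 1 kb from a transcription start, the ETS, YY1, ROR and SRF motifs did not pass (adjusted p = 0.17, 0.29, 0.40 and 0.65, Fisher's exact test).

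**Figure D3:**
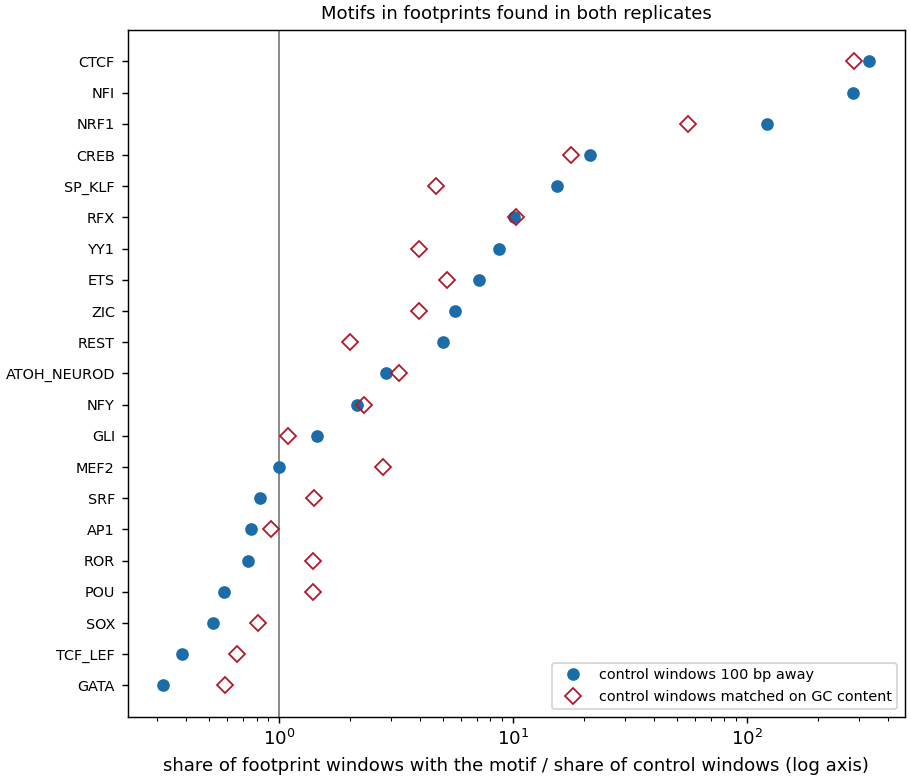
The plot gives, on a log axis, the share of footprint windows with each motif divided by the share of control windows, with filled circles for controls 100 bp away and open diamonds for controls matched on GC content. CTCF is at 333 and 286, ZIC at 5.65 and 3.96, and POU, SRF and ROR lie below 1 with the first controls and above 1 with the second. NFI has no diamond because 0 matched control windows held its motif, and HNF1, with 0 in both, is not drawn.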

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

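Footprints were the deposited signal that lay outside the measurements by peak, and they were examined only after their number had been seen. Outside the peaks of both lists lay 117674 footprints of replicate 1 (16.6%) and 87270 of replicate 2 (15.2%), where no peak was called. At least 99.5% of them touched positions with a false discovery rate under 0.05, as did 99.7% and 99.8% of the footprints inside peaks, and the positions so listed but outside the longer peak list covered 40.2 Mb and 28.5 Mb. Within 200 bp of a peak lay 90.2% and 94.6% of them. Whether they lie there because listed peaks cover only part of longer accessible tracts stays open: 97.3% and 99.0% of them lay in an unbroken stretch of such positions that held a peak, but 98.6% and 99.0% of all such positions did too, so the test was open to no other outcome. Their overlap with footprints of the other replicate was 37.1% in replicate 1, against 54.4% for footprints inside peaks of the longer list, and 61.4% against 62.2% in replicate 2. No biological explanation was tested, since the design has a single group.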

How the results depend on the processing

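The alternative without olfactory receptors and the one without genes over 2 Mb were chosen after the data had been seen. No paired analysis was possible because the design has a single group. The count of peaks of replicate 1 found in replicate 2 was 65817 with peaks above the median signal of each list, which are fewer, and between 103448 and 172141 under the other alternatives. Shared footprints numbered 269970 with reciprocal overlap. Genes with an open promoter ranged from 12558 to 14842, and from 14311 to 14470 with each replicate alone. The lists that differed in promoter accessibility numbered 12 to 14, and 12 to 13 with each replicate alone. The lists that differed in distal peaks numbered 7, and 4 with the median count, from 7 to 11 with each replicate alone, and 5 to 9 otherwise. The 11 came without replicate 2, and the cause was not tested. Motifs that differed numbered 16 to 20. The promoter share of peaks was 15.9% with a window of 500 bp and 27.8% with 2 kb, by the construction of the window, and 21.1% to 22.5% with each replicate alone. The number of reads is not known, and no alternative varied it, so what depth limits was not tested. Of single lists and motifs, 413 values kept their direction and side of the threshold, 20 lost the call and 20 gained it. Directions turned in the results that follow, and the cause was not tested. In promoter share, list minus other genes in percentage points, these were GABAergic interneurons (-11.3) and astrocytes (-17.5) with peaks above the median signal, and vascular (10.7), choroid plexus (23.8), isthmic (15.4) and forebrain (7.08) genes in the longer list. With each replicate left out in turn the forebrain list ranged from -28.0 to 21.3, the latter without replicate 2. In distal peaks, list minus random lists on the log2 scale, peaks above the median signal gave -0.15 for choroid plexus, 0.12 for Hox and -0.17 for liver genes. Random lists not matched on length gave 0.33 for vascular, -0.19 for housekeeping, -0.21 for liver and -0.30 for lymphocyte genes. Matching on promoter accessibility gave 0.20 for Hox and 0.081 for germ cell genes, a flank of 50 kb 0.34 for germ cell genes, the gene body alone -0.071 for lymphocyte genes, and the median count, in peaks, 0.5 for vascular genes. Leaving out a replicate gave -0.11 to -0.029 for lymphocyte genes and -0.081 to 0.13 for Hox genes. None of these turned values passed its test. In motifs, as log2 ratios, MEF2 was at -0.074 with a shift of 50 bp and -0.086 with windows of 50 bp, and ROR at 0.11 with windows of 50 bp. With matching on GC content ROR was at 0.47, and POU at 0.48 and SRF at 0.50 passed the test.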

Other observations

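The comparisons of promoter with distal footprints, the tests on promoters and distal peaks found in 1 replicate only and that of scaling were chosen after the data had been seen. Shared footprints within 1 kb of a transcription start and farther ones held different motifs. The E-box of ATOH and NEUROD proteins stood in 1.12% of 253707 distal windows and 0.225% of 112138 promoter windows, 4.99 times as often (adjusted p = 8.4e-205, Fisher's exact test over 22 motifs). CTCF was 4.80 times, ROR, the family of the Purkinje cell receptor gene Rora, 4.47 times, NFI 4.19 times, AP-1 2.90 times, MEF2 2.59 times and ZIC 2.35 times as frequent in distal windows, and SOX, GATA, SRF, and TCF and LEF were more frequent there too (adjusted p from 0, as computed, to 0.0040). In the other direction, YY1 was 55.3 times, ETS 19.1 times, SP and KLF 9.42 times, NRF1 9.07 times, CREB 5.26 times and NFY 2.79 times as frequent at promoters. Some of these ratios rest on few windows and are uncertain in size. Only 7 distal windows held the YY1 motif and 21 the ETS motif, and 9 promoter windows held the ROR motif. RFX (adjusted p = 0.051), GLI (0.051), POU (0.33), REST (0.88) and HNF1 (1) did not pass Fisher's exact test. The difference in base composition between promoters and distal regions was not removed here.

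Over the whole genome, 46.7% of the 13119 matches to the CTCF consensus had their centre in a shared footprint, a class that covers 0.236% of the sequence. The share was 27.8% of 1655 matches for NRF1, 16.4% of 1579 for NFI, 16.4% of 921 for YY1 and 12.1% of 51252 for SP and KLF. It was 2.49% of 150002 for ZIC and 0.856% of 295128 for ATOH and NEUROD. Below the share of the sequence were HNF1 (0 of 150), GATA (0.0463%), TCF and LEF (0.0716%), POU (0.0724%), SOX (0.111%), AP-1 (0.140%), MEF2 (0.170%), SRF (0.174%) and ROR (0.177%). Base composition was not matched here. With GC-matched controls MEF2, SRF and POU were more frequent in footprints (ratios 2.77, 1.41 and 1.40), while GATA, TCF and LEF, and SOX stayed lower. Shared regions, 1.09% of the sequence, held 1.56% of ROR, 1.33% of HNF1 (2 of 150), 1.29% of MEF2 and 1.29% of AP-1 matches. The shares of GATA, TCF and LEF, POU, SOX and SRF were below 1.09% there too.

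Several promoters of developmental transcription factors were open in replicate 1 and not in replicate 2. Among forebrain patterning genes 8 were open in replicate 1 only, Dlx1, Dlx2 and Sp8 among them, and 0 in replicate 2 only (adjusted p = 0.37 over 12 lists, exact binomial test against the 63.3% of all 599 such genes), and 6 of the 8 were in the longer list of replicate 2. A list of 54 regulators of other lineages, written before its values were seen, had 17 open in replicate 1 only and 0 in replicate 2 only (p = 0.00057, exact binomial test), and of its unshared distal peaks 291 were in replicate 1 and 12 in replicate 2, against 132 and 9 for forebrain patterning genes and 30676 and 19000 (61.8% in replicate 1) over the genome. Other lists had a share in replicate 1 above that of the genome too. Among them were unipolar brush cell (54 and 6), choroid plexus (28 and 3), Hox (12 and 1) and granule neuron genes (114 and 29). Lists with a lower share included astrocyte (15 and 12), general neuronal (54 and 60) and housekeeping genes (9 and 13). With 143390 top-ranked peaks from each replicate, the 8 forebrain promoters stayed open in replicate 1 only, so they did not rest on the peaks that this cut removed. Their promoter signals in replicate 1 were low all the same. They ran from 0.291 at Fezf2 to 0.600 at Dlx2, the 2.29 and 9.25 percentiles of promoter signals in that replicate. That cut removed only the weakest of the 155183 peaks of replicate 1 and left any difference in depth in place. The larger number of peaks in replicate 1 therefore stays open as an explanation. Forebrain tissue in replicate 1 stays open too. Distal regions of 18 mature forebrain markers had a median log2 difference at the 5.34 percentile of random lists of single distal regions matched on signal (0.40 against 0.49). Their unshared distal peaks, 41 in replicate 1 and 32 in replicate 2 (56.2%), gave no excess in replicate 1. A candidate explanation is that promoters with more CpG are called more readily in replicate 1: the median CpG observed over expected ratio was 0.469 for promoters open in replicate 1 only and 0.387 for those open in replicate 2 only, a difference of 0.0819 (p = 0.0035, permutation test with 100000 resamples), but both were below the 0.742 of promoters open in both, and the 8 forebrain promoters, with a median of 0.774, lay above most of the first class (upper quartile 0.673).

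Shared regions had a higher signal in replicate 2, although replicate 1 had more peaks and footprints. With regions ranked by the signal of replicate 1 alone, the median log2 difference of replicate 2 minus replicate 1 was higher by 0.39 in the highest decile than in the lowest (0.89 against 0.50), although it was 0.43 in the second. This argues against scaling by the number of reads, a single factor per library, as the whole of it, while a part stays open. The overall median fell from 0.51 to 0.21 when signals were counted in steps. That fall is fixed by the 2 steps, which lower every region by the same amount, so it cannot tell whether scaling makes a part. It would reflect the number of reads only if a step is a read. The difference rose with the mean signal of a region, from 0.34 in the lowest decile to 0.99 in the highest, with Spearman's rho of 0.312 across 115661 regions, which are not independent. This is consistent with a lower share of the reads of replicate 1 in strong regions, as a hypothesis. A difference between the tissue preparations was not tested and stays open.

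The log2 difference at distal regions, against random lists matched on signal, was low for several unlike lists. These random lists drew single distal regions independently, whereas the regions of a gene list lie together around few genes, such as 57 around 12 isthmic genes. Neighbouring regions are not independent, so the percentiles can be too extreme, and they were not adjusted for the number of lists. The medians were 0.17 for isthmic and hindbrain patterning genes (0.01 percentile), -0.15 for Hox clusters (0.05), 0.17 for the regulators of other lineages (0), 0.42 for granule neuron genes (0.535), 0.23 for forebrain patterning genes (0.8), 0.33 for olfactory receptors (1.595) and 0.21 for liver genes (1.78), and the other lists lay between the 5.34 and 93.4 percentiles. The low value of the forebrain patterning list is thus shared with lists of other tissues and leaves forebrain tissue in replicate 1 open.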
